A study of Mus musculus and Heterocephalus glaber with 4 samples.

How the data were processed

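Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in 4 libraries of cultured adult skin fibroblasts. Mouse and naked mole rat (Heterocephalus glaber) cells each gave 1 control library and 1 library of cells into which SV40 large T antigen had been introduced. Per the labels, all cells were at passage 16, grew in 15% serum at 3% oxygen and 5% CO2, and were kept at 37 °C (mouse) or 32 °C (naked mole rat). Each reaction took 50000 cells, transposition lasted 30 min, and the product was amplified for 10 to 12 cycles.

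The authors deposited 1 peak list per library, with 5 columns and no header: sequence name, start, end, peak name and a score. The peak names in the files begin with MACS, which names the peak caller, but no source used here states its settings or sets a version beside its name. The score in the deposited lists starts at 50.0 to 50.01 in every list, as a minimum-score filter would leave it. Its definition is not given in the sources used here. It was used to rank peaks within their own list, and the median per list is given as a description only, since the scores of different lists have no known common scale. The start and end coordinates are whole numbers of base pairs in the authors' files. They were read as BED intervals, and starts are printed 1-based. Per the submitters' processing notes, the build was mm9 and CASAVA, Bowtie, SAMtools and bedtools were used, with no roles given. The notes set version 1.4 beside CASAVA, and whether it belongs to that tool or to the peak caller is unsure. The 2 mouse lists hold chromosome names, and their positions on chromosome 1 run past the last gene of the GRCm38 gene table, whose coordinates were therefore not used. The 2 naked mole rat lists hold naked mole rat scaffold names, so mm9 cannot be their build, and which assembly release was used is not given in the sources used here. Peaks of the same list did not overlap each other. Nothing in the sources states that libraries were pooled.

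Read counts, depth and signal tracks were not analysed here, so the depth behind each peak is unknown. The number of peaks a caller reports grows with depth and with the signal over background. Differences in list size therefore cannot be separated from differences in depth. With 1 library per group there is no replicate error, no test was run between conditions, and no p-value is given. The 95% intervals are exact (Clopper-Pearson) binomial intervals over peaks. They cover counting error only and treat neighbouring peaks as independent, which by itself makes them too narrow. For the large T share of both lists they also treat the control and large T peaks of a shared site as independent. That by itself makes them too wide, so whether the intervals of this share are too narrow or too wide is unknown.

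Within a species, a peak was called shared when it overlapped a peak of the other list by at least 1 bp, and otherwise library-only. The chance level was taken from 100 random placements of the other list's peaks on the same chromosomes or scaffolds, whose lengths were taken as the end of the last peak. Base-level overlap was given as the Jaccard index (shared bases over bases covered by either list). Score deciles were formed within each list. Shared peaks were paired 1 to 1 by longest overlap to compare ranks, within the whole list and among shared peaks only, since ranks from lists of different lengths do not show a change. Ratios of scores between lists were also looked at and are not reported, because the scores have no known common scale. Peaks were counted per mouse chromosome and per naked mole rat scaffold with at least 300 peaks in both lists together and a last peak beyond 1 Mb. Consecutive library-only peaks on a sequence formed a run. The analyses of the highest score decile, of runs, of dense clusters and of scaffold JH602052 were chosen after seeing the data. The overlap, pairing and run functions were tested on simulated lists made from the 75120 mouse and 80661 naked mole rat control peaks: planted overlaps of 50% and 90% came back as 50.0% and 90.0%. On the deposited lists the overlap functions gave the same counts as bedtools 2.31.1. The pairing and run functions were tested on the simulated lists only, where shared peaks were exact copies of each other. There, only the number of pairs and the number of peaks in runs were checked. Which of several overlapping peaks were paired, and how long runs were, was thus not tested. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

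Regions were named by a rule set before the data were examined: the 5 highest-scoring peaks of each list and the 5 highest-scoring library-only peaks of each list. The 3 longest runs per list, and the chromosomes, scaffolds and clusters named, were chosen after their values were seen. Promoter shares and gene lists had also been planned. They were not computed, because no annotation of mm9 or of the naked mole rat scaffolds was used here, and the GRCm38 gene table cannot be set against these coordinates. Regions are therefore given by position without genes, exons or other annotation. No list of artefact-prone regions was applied. Alternatives set before the data were examined were the 50% highest-scoring peaks of each list, scaffolds over 1 Mb only, merging of peaks within 500 bp, a reciprocal overlap of 50%, a distance of 500 bp, 1 kb bins, equal numbers of peaks and ranks among shared peaks only. Amounts were taken as unmoved within 1.5-fold and shares within their 95% interval. For the Jaccard index, a ratio of bases, that interval was approximated by a binomial interval over peaks.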

Results

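ATAC-seq peak lists were compared between control fibroblasts and fibroblasts carrying SV40 large T antigen, a viral protein that binds p53 and the retinoblastoma family, in mouse and in the long-lived naked mole rat. The title of the series concerns reprogramming of naked mole rat cells to pluripotency and the stability of their epigenome. The mouse control list held 75120 peaks over 110.01 Mb and the mouse large T list 63258 peaks over 86.43 Mb. The naked mole rat control list held 80661 peaks over 115.02 Mb on 644 scaffolds, and the large T list 83297 peaks over 122.57 Mb on 669 scaffolds. Median peak widths were 1220 and 1158 bp in mouse control and large T cells, and 1210 and 1225 bp in naked mole rat control and large T cells. Each group had 1 library, so no value had a replicate error and no comparison between conditions was tested. Read depth is unknown, and the number of peaks called depends on it. Mouse positions are in mm9, per the submitters' processing notes, and naked mole rat positions are on scaffolds whose assembly release is not given in the sources used here.

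**Figure D1:**
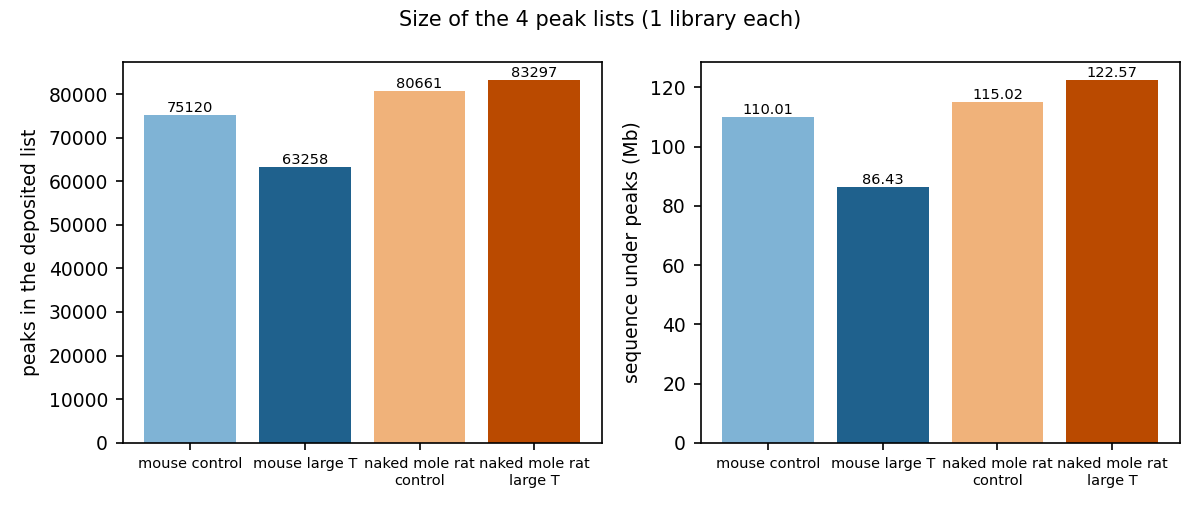
Bars give the number of peaks (left) and the sequence under peaks in Mb (right) in each of the 4 deposited lists, 1 library per bar and no error bars. The mouse large T list is the shortest with 63258 peaks and the naked mole rat large T list the longest with 83297.

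In mouse fibroblasts, fewer sites were called open in large T cells than in control cells. The large T list had 15.8% fewer peaks and covered 21.4% less sequence. Of the control peaks, 53516 (71.2%, 95% interval 70.9 to 71.6) overlapped a large T peak and 21604 did not. Of the large T peaks, 53917 (85.2%, 85.0 to 85.5) overlapped a control peak and 9341 did not. Random placement gave a mean of 6.75% for the control peaks and 7.95% for the large T peaks. The lists shared 72.82 Mb, a Jaccard index of 0.589. Broad peaks of at least 2 kb made up 18.2% of the control list (13698 peaks) and 15.2% of the large T list (9644 peaks).

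The 5 highest-scoring mouse sites of each list were found in both lists. No list of artefact-prone regions was applied, so artefacts among these sites were not excluded. The scores are the authors' and ranks hold within 1 list. The highest-scoring peak of both lay on chromosome 1, at 24618568 to 24620155 in control cells and 24618464 to 24620155 in large T cells. The peak on chromosome 2 at 98506393 to 98507859 ranked 2 in the control list, and its large T counterpart at 98506392 to 98507958 ranked 4. The peak on chromosome 18 at 21457074 to 21459849 ranked 3 in control and 7 in large T cells. The peak on chromosome 8 at 20019376 to 20020843 ranked 4 and 5, and that on chromosome 12 at 119538025 to 119541688 ranked 5 and 3. The large T list also had the peak on chromosome 8 at 72239902 to 72241590 at rank 2, and its control counterpart ranked 9.

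Mouse sites called in 1 list were mostly narrow and low in score. Control-only peaks had a median width of 920 bp against 1420 bp for shared control peaks, and 1.92% against 24.8% were at least 2 kb wide. In the lowest score decile of the control list, 70.2% of peaks had no large T counterpart, and in the highest decile 3 of 7512 peaks (0.0399%, 0.0082 to 0.117) had none. These 3 were on chromosome 16 at 71510809 to 71512619, 328411 bp from the nearest large T peak, on chromosome 11 at 81100371 to 81101774, and on chromosome 14 at 20604371 to 20606483. The next highest control-only peaks were on chromosome 13 at 96950506 to 96951373 and on chromosome 2 at 68787371 to 68788659. In the large T list, 8 of 6326 peaks of the highest decile were found there only. The highest was on chromosome 9 at 3000001 to 3003249, with the closest control peak 10707 bp away. Whether this peak is an artefact was not examined, since no list of artefact-prone regions was applied. Those on chromosome 18 at 61823693 to 61826716 and 21586931 to 21588440, on chromosome 10 at 127102284 to 127106172 (3889 bp wide) and on chromosome 19 at 52627610 to 52629296 followed.

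Library-only mouse peaks also lay next to each other. The longest run of control-only peaks held 13 peaks over 0.453 Mb of chromosome 8 (15206199 to 15659578), with no large T peak inside. It was followed by 12 peaks over 1.08 Mb of chromosome 7 (131401789 to 132481088) and 11 peaks on chromosome 1 (5215627 to 6181240). These lengths did not exceed the range of chance: in 100 shuffles of the control-only calls within score deciles, the longest run averaged 9.3 peaks and reached 13. The longest run of large T-only peaks held 11 peaks over 0.27 Mb of chromosome 9 (112942024 to 113212385), with no control peak inside. Runs of 8 large T-only peaks lay on chromosome 2 (133497047 to 133917516), with no control peak inside, and on chromosome 9 (111412435 to 111725128), with 1 control peak inside.

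In naked mole rat fibroblasts, slightly more sites were called open in large T cells than in control cells. The large T list had 3.27% more peaks and covered 6.56% more sequence. Of the control peaks, 62067 (76.9%, 76.7 to 77.2) overlapped a large T peak and 18594 did not. Of the large T peaks, 61897 (74.3%, 74.0 to 74.6) overlapped a control peak and 21400 did not. Random placement gave means of 9.80% and 9.48%. The lists shared 86.35 Mb, a Jaccard index of 0.571. Broad peaks of at least 2 kb made up 17.3% of the control list and 19.3% of the large T list.

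The 5 highest-scoring naked mole rat sites of each list were found in both lists. As in mouse, artefacts among them were not excluded. The highest-scoring peak of both lay on scaffold JH602049, at 6170801 to 6172289 in control cells and 6170857 to 6172588 in large T cells. Peaks on JH602073 (71219 to 73555 in control cells) and JH602043 (45697208 to 45699795) ranked 4 and 5 in both lists. The peak on JH602235 at 3606 to 4961 ranked 2 in control and 3 in large T cells. The peak on JH602196 at 2073869 to 2074965 ranked 3 in control and 12 in large T cells. A peak on the short contig AHKG01111715 at 2 to 1411 ranked 2 in large T and 17 in control cells.

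High-scoring control sites without a large T counterpart were more frequent in the naked mole rat lists than in the mouse lists, a comparison chosen after seeing the data. In the highest score decile of the naked mole rat control list, 130 of 8066 peaks (1.61%, 1.35 to 1.91) had none, on 84 scaffolds with at most 6 on 1 scaffold. The highest were on JH602133 at 6826299 to 6828000, JH602053 at 4283918 to 4285648, JH602161 at 605477 to 606886, and JH602083 at 1912917 to 1915585 and 15819 to 17527. The peak on JH602053 ranked 736 of the 80661 control peaks and lay 489187 bp from the nearest large T peak. In the reverse direction, 15 of 8330 large T peaks of the highest decile (0.18%, 0.10 to 0.30) had no control counterpart. Of these, the 2 highest lay at the very start of contigs on which the control list had no peak, AHKG01112324 at 3 to 1652, which ranked 8 of the 83297 large T peaks, and AHKG01111111 at 4 to 4566, which ranked 818. They were followed by JH602080 at 14218493 to 14220494, JH602170 at 4313042 to 4314641 and JH602066 at 23421812 to 23423298. In the lowest decile, 52.0% of control and 62.0% of large T peaks were library-only.

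**Figure D2:**
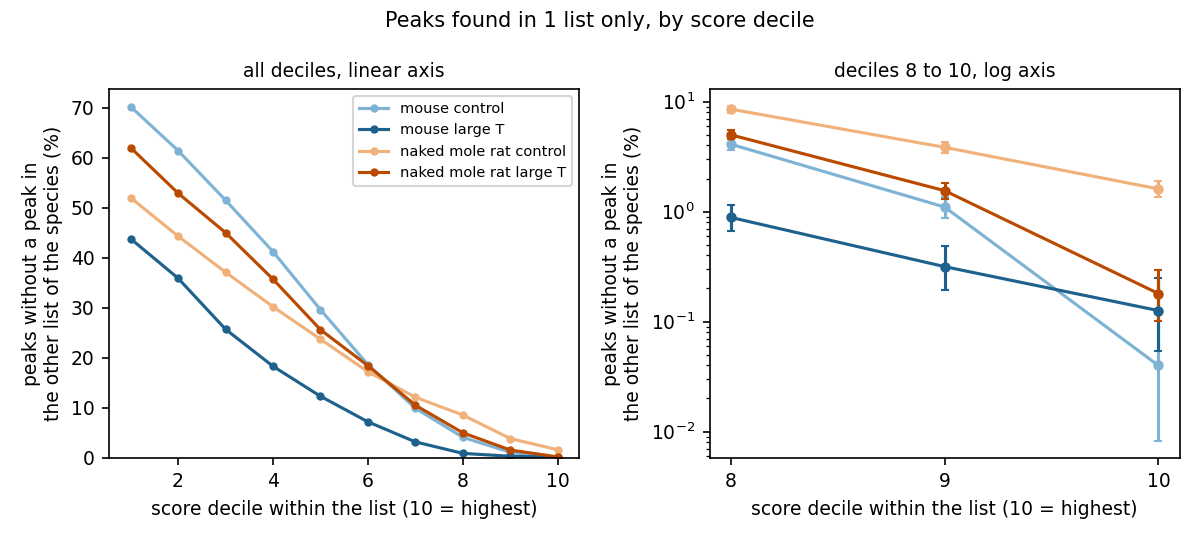
Points give the percentage of peaks in each score decile of a list that have no overlapping peak in the other list of the same species, for all deciles on a linear axis (left) and for deciles 8 to 10 on a log axis with exact 95% binomial intervals (right). In the highest decile the naked mole rat control list stands at 1.61% and the mouse control list at 0.0399%.

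Several long blocks of naked mole rat sequence carried peaks in 1 list only. On JH602053, 24 consecutive control-only peaks spanned 1.31 Mb (3848022 to 5156022) and included the site at 4283918 named above. Blocks of 16 and 15 control-only peaks lay on JH602060 (24734488 to 25479864) and JH602049 (16022611 to 16643480). On JH602111, 21 consecutive large T-only peaks spanned 1.41 Mb (4318584 to 5724813). Blocks of 19 and 17 large T-only peaks lay on JH602052 (6016639 to 6818593) and JH602153 (1603895 to 2996668). None of these 6 blocks held a peak of the other list.

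Set side by side, the share of control peaks with a large T counterpart was higher in naked mole rat (76.9%) than in mouse (71.2%), a difference of 5.71 percentage points. The share of large T peaks with a control counterpart was lower in naked mole rat (74.3%) than in mouse (85.2%), a difference of -10.9 points. The lists differ in length between species and also within a species. Large T peaks numbered 84.2% of control peaks in mouse and 103.3% in naked mole rat. The 63258 highest-scoring peaks of every list were therefore compared. The share of control peaks with a counterpart was lower in naked mole rat (75.4%) than in mouse (78.5%), a difference of -3.14 points. The share of large T peaks with a control counterpart was then 75.3% in naked mole rat and 79.3% in mouse. With equal numbers within a species only, a setting chosen after seeing the data, the difference for control peaks was -2.73 points. The order of the species for control peaks thus depended on whether list lengths were equalised, and equalising them within a species was enough to reverse it. With 1 pair of libraries per species, neither order was tested against replicate error, and the species also differed in culture temperature (37 and 32 °C).

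Scores of shared sites were ordered alike in the 2 lists of a species. Across 53375 mouse pairs Spearman's rho was 0.79, and across 61517 naked mole rat pairs it was 0.73; pairs are sites within 1 comparison of libraries and not independent replicates. Ranked within the whole list, 5.3% of mouse sites stood over 25 percentile points higher in the large T list and 13.2% over 25 points lower. Ranked among shared peaks only, which removes the difference in list length, the shares were 8.39% and 8.44%. In naked mole rat they were 11.6% and 9.59% within the whole list, and 9.5% and 10.8% among shared peaks only.

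Large T peaks were fewer than control peaks on every mouse autosome and on the X chromosome, by unequal shares. Over the whole list, large T peaks numbered 84.2% of control peaks. On the X chromosome they numbered 74.2% (1621 against 2185 peaks) and on chromosome 4 they numbered 92.3% (3721 against 4031). The large T share of both lists was 42.6% on X and 48.0% on chromosome 4, and 44.1% and 47.7% among the 50% highest-scoring peaks of each list, where X lay closer to the list-wide share. The exact 95% interval of the large T share of both lists excluded the list-wide 45.7% on 8 of 21 chromosomes. If all peaks were independent draws, 1.1 would be outside by counting error alone. Most sites were shared and enter the counts of both lists, so 1.1 is not an exact chance level. Chromosomes 3, 4, 8 and 13 lay above the list-wide share, and chromosomes 1, 5, 10 and X below. The Y chromosome carried 11 control and 12 large T peaks.

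Among naked mole rat scaffolds, JH602052 had the highest ratio of large T to control peaks. It carried 1222 large T and 888 control peaks, 137.6% of the control number, against 103.3% over the whole list. The large T share of both lists was 57.9% (55.8 to 60.0) on this scaffold, the only 1 of 138 scaffolds whose interval lay above the list-wide 50.8%. On JH602052, 41.2% of large T peaks and 17.6% of control peaks were library-only. The intervals of 6 scaffolds lay below the list-wide value. The lowest was JH602116 with 154 large T and 232 control peaks, followed by JH602110 with 231 and 301. If all peaks were independent draws, 6.9 of the 138 intervals would exclude the list-wide value by counting error alone. Most sites were shared and enter the counts of both lists, so 6.9 is not a chance level for these scaffolds. Whether the scaffolds varied more than chance was not tested.

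**Figure D3:**
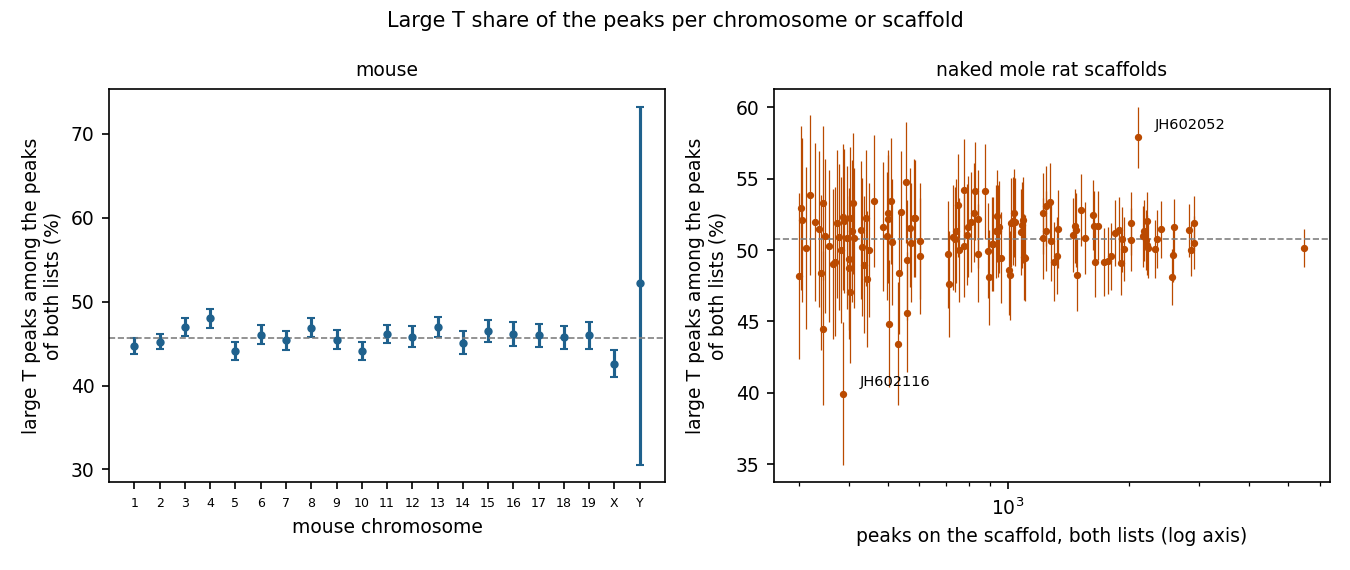
Points give the percentage of large T peaks among the peaks of both lists, with exact 95% binomial intervals, for each mouse chromosome (left) and for each of 138 naked mole rat scaffolds against its number of peaks on a log axis (right), and dashed lines mark the list-wide 45.7% and 50.8%. JH602052 lies at 57.9% and JH602116 at 39.9%.

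**Figure D4:**
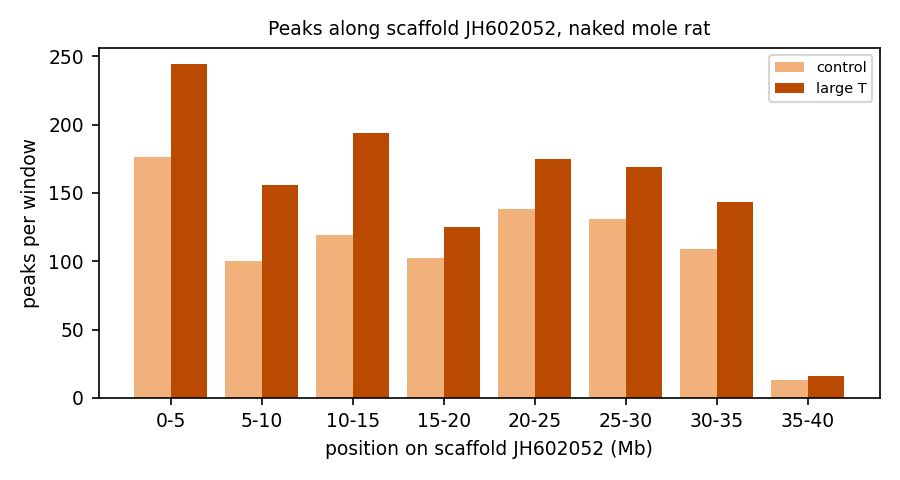
Bars give the number of naked mole rat control and large T peaks in windows of 5 Mb along scaffold JH602052, whose last peak ends at 35359212. The large T number is the higher of the pair in every window, with 125 against 102 peaks at 15 to 20 Mb, where the ratio is lowest, and 194 against 119 at 10 to 15 Mb, where it is highest.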

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

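Of the tests in this part, that of large T peaks within 20 kb was set before its result was seen; the tests of library sensitivity and those on scaffold JH602052 were chosen after. With 1 library per group, large T and control cells differed in opposite directions in the 2 species for 5 measures, and none of these differences was tested. All 5 were taken from the same lists, so they are not separate lines of evidence. The number of peaks, large T minus control, differed by -11862 in mouse and 2636 in naked mole rat. Covered length differed by -23.58 Mb in mouse and 7.55 Mb in naked mole rat. Median peak width differed by -62 bp and 15 bp, and the share of peaks of at least 2 kb by -2.98 and 1.99 percentage points. The median score within the list differed by 4.12 in mouse and -5.97 in naked mole rat, values that say nothing about sensitivity because the scores have no known common scale.

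The shorter mouse large T list may reflect a library of lower sensitivity, through fewer reads or less signal over background. Lost sites should then be weak ones, and 0.0399% of the highest score decile of control peaks lacked a large T peak, against 70.2% of the lowest decile. Large T peaks without a control peak showed a gradient of the same kind (0.126% of the highest and 43.8% of the lowest decile), so it does not tell which library was less sensitive. An effect of large T antigen, which the design names, also stays open and untested. Read numbers, which would help to separate these explanations, were not analysed here.

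The 130 high-scoring naked mole rat control peaks without a large T peak lay on 84 scaffolds. Whether the large T library had a lower overall sensitivity could not be decided. Its list was longer than the control list by 2636 peaks, a value known before the test was chosen. List length also depends on depth, which is unknown, so it does not measure sensitivity at these sites. Absence of stretches of sequence from the large T cells would leave few large T peaks nearby; 49.2% of the 130 had 1 within 20 kb, between the limits of 10% and 50% set beforehand, so for these peaks this explanation and others cannot be told apart. For 38 of the 130 both neighbouring control peaks were also control-only, and for 31 both were shared. An effect of large T antigen, and a difference between animals or cell clones, on which the labels say nothing, stay open and untested.

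JH602052 was singled out after the fact as the highest of 138 scaffolds (log2 ratio 0.46), while JH602116, which was not examined further, lay farther from the list-wide ratio on the low side (-0.59), and the JH602052 excess of large T peaks may reflect a copy number that differed between the cells along the whole scaffold. The ratio exceeded the list-wide ratio in all 7 windows of 5 Mb with at least 50 peaks. These windows split the same counts by which the scaffold was picked, so they are no independent support. The median rank shift of JH602052's shared peaks towards the large T list was above that of 97.8% of scaffolds. The scaffolds with larger shifts, JH602221, JH602141 and JH602145, carried large T peaks at 106.1%, 111.0% and 109.2% of control. A large shift thus also occurs without such an excess. A change confined to the 2 windows of highest ratio would leave the rest near the list-wide ratio. The remaining windows are part of the counts by which the scaffold was picked, which may raise their ratio, so they cannot decide this. Without the 2 windows an excess remained: the log2 ratio was 0.38 (95% interval 0.24 to 0.53) against 0.05 over the whole list. That interval includes the 0.28 of the next highest scaffold, JH602162. It treats the 2 lists as independent counts, and the counting error of JH602162 was not taken into account. Whether the rest of JH602052 stood apart from every other scaffold was thus not settled, although a first comparison of the bare values had it so. An effect of large T antigen on chromatin along the scaffold stays open and untested, as does base composition, since coverage and sequence were not used here.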

How the results depend on the processing

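Each group had 1 library, so no library could be left out. No paired analysis was possible because each group has 1 library and no replicate numbers. Of the main results under other settings, 44 values stayed within 1.5-fold (amounts) or within the 95% interval (shares), 39 moved further and 2 changed sign; unless stated, the cause was not tested. The planned promoter and gene-list alternatives were not run for lack of an annotation. Leaving out unplaced sequences removed no mouse peak, so it tests nothing there, although its values count among the 44. The 1.5-fold limit is wider than the differences in peak number between large T and control lists (-15.8% in mouse, 3.27% in naked mole rat). Amounts within that limit thus do not show that these differences hold. Depth is unknown and limits every list size.

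Keeping the 50% highest-scoring peaks of each list lowers amounts by construction. It left 31629 (mouse large T), 37560 (mouse control), 41648 (naked mole rat large T) and 40330 (naked mole rat control) peaks over 54.64, 69.57, 77.18 and 71.98 Mb. Among these, 72.7% of mouse control, 86.4% of mouse large T, 76.2% of naked mole rat control and 73.8% of naked mole rat large T peaks were shared, with Jaccard indices of 0.596 and 0.559. In the same order of lists, a reciprocal overlap of 50% gave 67.7%, 80.4%, 72.3% and 69.98%, and a distance of 500 bp gave 71.9%, 85.98%, 78.05% and 75.3%. Equal numbers of peaks within a species gave 78.5%, 79.3%, 75.8% and 75.6%, and a Jaccard index of 0.599 in mouse. Merging moved the naked mole rat shares to 77.4% and 74.7%. Bins of 1 kb gave Jaccard indices of 0.613 and 0.592.

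The difference between species in the share of control peaks with a counterpart (naked mole rat minus mouse) was 5.71 points with all peaks and 4.59 with reciprocal overlap. It reversed to -3.14 with 63258 peaks in every list and to -2.73 with equal numbers within a species, the latter chosen after seeing the data. In mouse, equal numbers trim only the longer control list, and the share moved from 71.2% to 78.5%. For large T peaks the difference was -10.9 points, -10.4 with reciprocal overlap, -3.97 and -3.72 with equal numbers. Shares of shared sites moving over 25 percentile points up and down were 5.3% and 13.2% in mouse with whole-list ranks, and 8.39% and 8.44% among shared peaks only. In naked mole rat they were 11.6% and 9.59%, against 9.5% and 10.8%. The high-scoring control peaks without a large T peak numbered 0 in mouse and 3 in naked mole rat among the 1000 highest, and 232 and 738 among the 20000 highest, settings chosen after seeing the data. Rotating all peaks of a sequence together, also chosen after, gave chance levels of 6.90%, 8.22%, 10.2% and 9.83%, against 6.75%, 7.95%, 9.80% and 9.48% by random placement.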

Other observations

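Peak-dense stretches were found in all 4 lists when peaks within 12.5 kb of each other were joined and groups of at least 10 peaks kept, a definition chosen after seeing the data. The mouse control list had 158 such clusters and the large T list 87, and 31.0% and 55.2% of them overlapped a cluster of the other list. The naked mole rat lists had 170 (control) and 194 (large T), and 46.5% and 40.7% overlapped. Overlapping clusters numbered 49 (control) and 48 (large T) in mouse and 79 in each naked mole rat list. The percentages of a species thus differ mainly through their totals. Cluster numbers also depend on list length, and no equal-length version or chance level is given here. The clusters with the most peaks were largely open in both conditions. On mouse chromosome 8 at 11244058 to 11413294, 22 large T peaks faced 23 control peaks. On mouse chromosome 12 at 70519354 to 70644041, 20 control peaks faced 19 large T peaks. In naked mole rat, JH602145 held 24 large T and 24 control peaks at 4651462 to 4850011, and 22 control and 20 large T peaks at 1745745 to 1934180.

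All tests of runs in this part were chosen after the observed run lengths were seen. Library-only peaks may differ between the lists in neighbourhoods rather than singly. If single peaks came and went independently, shuffling the library-only calls within score deciles 100 times should give runs as long. The longest run was 24 peaks in the naked mole rat control list against at most 11 in the shuffles, 21 against 12 in the naked mole rat large T list, and 11 against 10 in the mouse large T list, where 25 runs of at least 5 peaks compare with at most 9. In the mouse control list the longest run, 13, was matched by the shuffles, but 266 runs of at least 5 peaks exceeded their highest of 147, a count put in place of the longest run once that had not exceeded the shuffles. Regional differences in detection, copy number and chromatin would each give such runs and were not separated. Of the 178 runs of at least 5 control-only peaks in naked mole rat, 50 (28.1%) held a large T peak inside, so the whole stretch was not absent from the large T cells there. The other runs, including the 3 longest, held none, and for them absence of the stretch stays open.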
